A study of Mus musculus with 6 samples.

How the data were processed

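RNA sequencing was carried out on tumour cells from iBIP mice, a melanoma model in which a mutant BRAF transgene is switched on by doxycycline and floxed alleles, among them Ink4a/Arf (Cdkn2a), are deleted in melanocytes by tamoxifen-activated Cre, per the labels' protocols. The same labels state that the cells came from ear tumours of iBIP mice that were either wild type for Kmt2d or carried 2 floxed Kmt2d alleles. They assign 3 libraries to KMT2D WT and 3 to KMT2D KO. The labels' extraction protocol names cerebellar tissue as the source of the RNA, while the other labels name cultured tumour cells. The labels do not say whether the 3 libraries of a group came from separate cultures, tumours or mice, so all p-values measure only the spread between these libraries, which may be technical, and a difference between groups cannot be separated from a difference between the tumours from which the cells were taken.

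The deposited values were whole-number counts of fragments per gene for 24391 genes, made with featureCounts 1.5.2 over exons of an mm9 gene annotation, per the file headers. STAR, HTSeq and mm9 are named in the submitters' processing notes, which do not give their roles or versions. The command recorded in the file headers set no strand option, so fragments from both strands were counted. It also set no option for fragments that map to several places or overlap several genes, and featureCounts by default leaves both kinds out. Counts of genes with near-identical copies (such as H2, Oas, Gbp, Ccl, Ifit and Serpinb9 family members, Gapdh and Eno1) and of genes that overlap another gene (such as H19, Igf2, Slc24a5, Nid2, Ncam1, Ccne2 and Ankrd37) are therefore uncertain. The files hold gene totals, so single exons of Kmt2d were not analysed here. Coordinates are those of the files, in mm9 and counted from 1. The reference genome at hand was of another build and was not used here.

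The total count was 56383873, 59360068 and 43168605 in KMT2D WT replicates 1, 2 and 3, and 79718782, 63516302 and 55594979 in KMT2D KO replicates 1, 2 and 3. A floor of 3 counts over the libraries of a group corresponded to 0.0182 CPM in KMT2D WT and 0.0157 CPM in KMT2D KO. For genes with 1 to 3 counts in a group, the ratio of the groups was given with an exact 95% binomial interval. Intervals and floors cover counting error only, since fragments without molecular identifiers are not independent molecules. CPM, the counts relative to the size of the library, were computed on library sizes scaled by TMM factors, which lay between 1.036 and 1.044 in KMT2D WT and between 0.957 and 0.967 in KMT2D KO.

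Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default low-count filter by group and a model with the group only. The filter left 14579 genes, and 3978 genes had no count in any library. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and the calls with an absolute log2 fold change above 1 were counted as well. The standard error of a log2 fold change was taken as its size divided by the square root of F. Adjusted p-values of single genes in the text are from this test, and log2 fold changes are KMT2D KO minus KMT2D WT.

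Before the data were examined, 29 gene lists with 625 genes in all were fixed, covering pathways, complexes and markers of other cell types. All 625 genes were found in the files, 7 of them under an older symbol. The 23 lists with at least 5 tested members were compared with all other tested genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over these lists. The test was repeated with a correlation estimated for each list. The same test was applied to the genes of each of 20 chromosomes.

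The genes named in the text followed a rule that was also fixed beforehand. It took Kmt2d, Cdkn2a, Braf, Igfbp5 and Igf1r in every case. Some genes that the rule took are not reported here. It added the 6 largest rises and 6 largest falls among called genes with a mean of at least 10 CPM in the higher group, no overlap between the libraries of the groups, and a symbol that was not a clone or predicted-model name. From each list it took up to 2 called members that rose and 2 that fell, those with the largest absolute log2 fold change among members with a mean of at least 1 CPM. From a list without a called member it took the 1 or 2 most abundant. Genes outside this rule are said to have been chosen after their values were seen. The same holds for Malat1, Xist, Pdgfra, Dcn, Lum and Fap.

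Alternatives were RLE size factors, library size without further scaling, DESeq2 1.42.0, limma voom, no low-count filter, a filter at a mean of 1 CPM, robust empirical Bayes, the replicate number as a block, a test against an absolute log2 fold change of 1 (glmTreat), fry in place of camera, and leaving out each library in turn. Leaving out 4 abundant non-coding RNAs, and centring fold changes on each chromosome's median, were added after the data were seen. Not every alternative was run for lists and chromosomes. Figures were drawn with matplotlib 3.10.9.

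The tests were checked on simulated counts drawn from the means and library sizes of the comparison of KMT2D KO with KMT2D WT over 14389 genes. At true absolute log2 fold changes of 0.5, 1, 2 and 3, the share of changed genes recovered was 72%, 76%, 83.7% and 100%. Of 174 calls, 5.17% were false. Camera called the 1 shifted set of 25 genes and 0 of the 19 unshifted sets. Simulated genes were drawn independently of each other, and few were changed. The check therefore does not cover lists of correlated genes or a comparison in which most genes differ. In the data, the estimated correlation reached 0.58, for oxidative phosphorylation, against the preset 0.01.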

Results

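Gene expression was measured by RNA sequencing in cultured iBIP mouse melanoma cells with intact Kmt2d (KMT2D WT, 3 libraries) and in iBIP cells from mice with floxed Kmt2d alleles (KMT2D KO, 3 libraries). Kmt2d encodes a histone H3 lysine 4 methyltransferase that acts mainly at enhancers. Total counts ranged from 43168605 to 59360068 in KMT2D WT and from 55594979 to 79718782 in KMT2D KO. The non-coding RNA Malat1 took 3.44% to 3.82% of the counts in KMT2D WT and 2.19% to 2.32% in KMT2D KO. Across tested genes, log2 CPM correlated between libraries of the same group with Pearson coefficients of 0.981 to 0.996, and between libraries of different groups with coefficients of 0.868 to 0.882. Counts of libraries of the same group differed by more than sampling noise, with chi-square values of 11.6 to 26.4 per degree of freedom, so no library was a second copy of another. The comparison asks how expression differed between melanoma cells labelled KMT2D KO and KMT2D WT.

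The targeted gene was examined first. Kmt2d (mm9 chromosome 15, 98662100 to 98701636, minus strand) gave 79.7, 87.6 and 101 CPM in KMT2D WT replicates 1, 2 and 3, and 73.0, 69.3 and 79.8 CPM in KMT2D KO replicates 1, 2 and 3. The means were 89.3 ± 10.6 and 74.0 ± 5.32 CPM (SD, n = 3), a log2 fold change of -0.27 (SE 0.08, edgeR adjusted p = 0.0075), and the libraries of the groups overlapped. Without KMT2D KO replicate 2 the gene was no longer called (log2 fold change -0.21, adjusted p = 0.058), and without KMT2D WT replicate 3 the value was -0.17. Over all alternatives the adjusted p lay between 0.00057 and 1, the highest being that of the test against a log2 fold change of 1. Counts summed over the whole gene need not fall when part of a gene is deleted, so this value does not show whether the floxed part was lost.

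Cdkn2a and Braf, which are targeted or mimicked by engineered alleles in iBIP mice, were read out as whole-gene counts as well. Cdkn2a, which encodes the cell cycle inhibitors Ink4a and Arf (chromosome 4, 88920377 to 88940523), rose from 13.3 ± 0.614 to 24.4 ± 2.34 CPM (SD, n = 3), a log2 fold change of 0.87 (adjusted p = 7.4e-07). Counts at the mouse Braf gene (chromosome 6, 39553237 to 39675462) rose from 51.3 ± 4.42 to 74.4 ± 0.126 CPM, a log2 fold change of 0.54 (adjusted p = 3.4e-06). Whether fragments of the BRAF transgene were counted there was not examined. All tested genes of chromosome 6 had a median log2 fold change of 0.42, so the rise of Braf lay near that of its chromosome. Because Cre may remove only part of a floxed gene, the gene total of Cdkn2a does not give the level of functional transcripts.

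**Figure D1:**
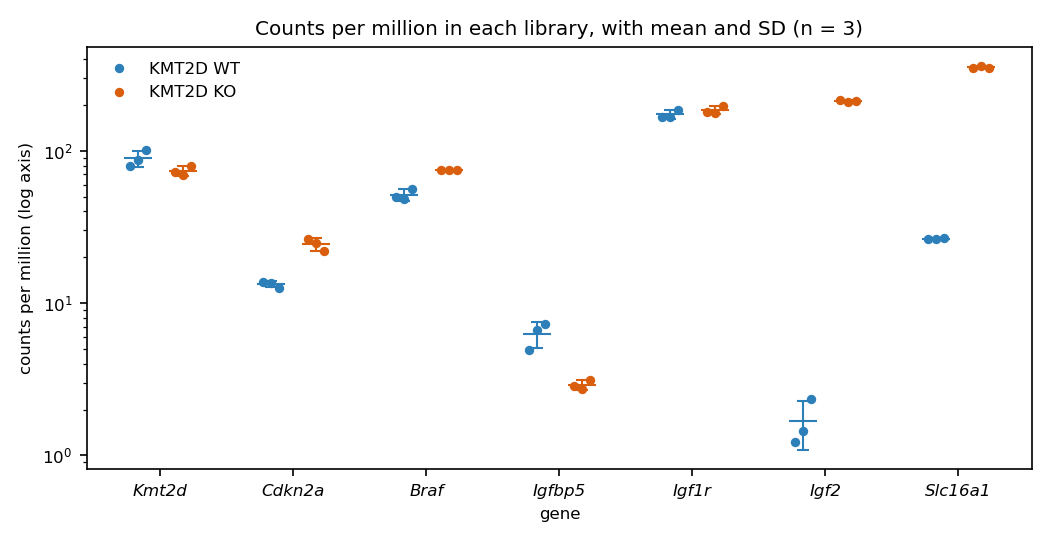
CPM (log axis) of 7 genes in each library, with KMT2D WT in blue and KMT2D KO in orange. Points are libraries, horizontal bars are means and whiskers are SDs (n = 3). Kmt2d and Igf1r overlap between the groups, while Igf2 rises from a mean of 1.68 to 211 CPM.

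Expression differed between the groups in most tested genes. Of 14579 genes, 10345 (71.0%) were called by edgeR, 5164 higher and 5181 lower in KMT2D KO. With an absolute log2 fold change above 1, 3902 genes were called, 2028 higher and 1874 lower. Libraries of the 2 groups did not overlap in 10832 genes (74.3%), where chance gives 10%. Tested against an absolute log2 fold change of 1 with glmTreat, 2823 genes were called. The biological coefficient of variation between libraries of a group was 7.94%, and scaling by library size alone moved the median log2 fold change of all genes by -0.11.

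Several of the largest rises were in genes that were nearly silent in KMT2D WT. Chrdl1, a BMP antagonist (chromosome X, 139720217 to 139828805), rose from 0.724 ± 0.114 to 577 ± 10.2 CPM (SD, n = 3), a log2 fold change of 9.63 (SE 0.09, adjusted p = 7.3e-18). Srpx on chromosome X rose by 9.26 to 135 CPM, and Ccdc129 on chromosome 6 by 8.90 to 61.8 CPM. Vax2, a homeobox transcription factor of the ventral eye, rose by 8.81 to 52.7 CPM. H19, an imprinted long non-coding RNA (chromosome 7, 149761435 to 149764051) that contains Mir675, rose by 8.79 to 138 CPM. Lipo1 rose by 8.74 to 21.6 CPM. The adjusted p of these 6 genes was at most 3.0e-13.

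The largest falls left almost no counts in KMT2D KO. Ccdc85a (chromosome 11, 28285684 to 28484324) had 27.3 ± 1.12 CPM in KMT2D WT and 2 counts over the KMT2D KO libraries, a ratio of 2605 (95% interval 721 to 21516). Rspo4, a secreted activator of Wnt signalling (chromosome 2, 151668663 to 151700404), had 13.6 ± 2.86 CPM in KMT2D WT and 1 count in KMT2D KO, a ratio of 2554 (458 to 100919). Sall1, a zinc finger transcription factor, had 11.6 ± 1.02 CPM in KMT2D WT and 2 counts in KMT2D KO, a ratio of 1104 (305 to 9120). Serpinb9e fell from 262 to 0.310 CPM (log2 fold change -9.74). Nefl, the neurofilament light chain, fell from 53.6 to 0.0971 CPM (-9.12), and Pcdh9, a protocadherin, fell from 11.7 to 0.0193 CPM (-8.99, 4 counts in KMT2D KO). The adjusted p of these 6 genes was at most 2.4e-12.

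Interferon-stimulated genes were higher in KMT2D KO without exception, as 30 of 30 tested members were called higher. Their median log2 fold change was 3.80. Oasl1, a member of the oligoadenylate synthetase-like family, rose from 0.0290 to 7.49 CPM (7.86), and Mx1, an antiviral GTPase, from 0.285 to 37.3 CPM (7.02). Chosen after their values were seen, Irf7 rose from 5.96 to 105 CPM (4.14) and Ifit1 from 9.68 to 504 CPM (5.71). Of 16 tested antigen presentation genes, 14 rose, 0 fell and 2 were not called, with a median of 1.88. Among them were H2-Ab1, an MHC class II chain (0.264 to 4.38 CPM, 4.01), and Tap1, the peptide transporter (12.2 to 92.9 CPM, 2.92). Camera called both lists (adjusted p = 3.4e-59 and 2.4e-10), and these were the lists that it also called with an estimated correlation (adjusted p = 0.026 for both). Tested immune cell markers had a median of -1.19 in the same comparison, with 1 higher, 5 lower and 2 not called.

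Inflammatory cytokine genes moved both ways. Of 22 tested, 13 rose, 7 fell and 2 were not called, with a median of 0.88. The chemokine genes Ccl5 (0.392 to 56.0 CPM, 7.09) and Cxcl12 (4.55 to 121 CPM, 4.73) rose, while Il11 (44.1 to 2.24 CPM, -4.28) and Ccl7 (822 to 279 CPM, -1.56) fell. Camera called the list higher (adjusted p = 0.012), but not with an estimated correlation (adjusted p = 0.39).

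Most glycolysis genes were higher in KMT2D KO, with 20 of 26 higher, 4 lower and 2 not called, and a median log2 fold change of 1.11. Slc16a1, which encodes the lactate transporter MCT1, rose from 26.5 ± 0.391 to 354 ± 4.46 CPM (3.74), and the aldolase gene Aldoc from 0.451 to 17.8 CPM (5.26). The muscle enolase gene Eno3 fell from 47.0 to 17.5 CPM (-1.42), and Pfkfb4, a regulator of phosphofructokinase, from 7.41 to 4.03 CPM (-0.88). Chosen after their values were seen, the glucose transporter gene Slc2a1 rose from 106 to 328 CPM (1.63), the hexokinase gene Hk2 from 78.0 to 269 CPM (1.79) and the lactate dehydrogenase gene Ldha from 617 to 1341 CPM (1.12). Camera called the list (adjusted p = 8.6e-11), and the call was lost with an estimated correlation (adjusted p = 0.15).

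Genes of the hypoxia response, a list that holds targets of HIF, were higher in 15 of 20 cases, lower in 3 and not called in 2, with a median of 1.11. The mitophagy receptor gene Bnip3 rose from 62.3 to 355 CPM (2.51) and Ankrd37 from 0.652 to 3.52 CPM (2.42). The prolyl hydroxylase gene Egln3 fell from 40.2 to 19.8 CPM (-1.02) and the endoplasmic reticulum oxidase gene Ero1l from 258 to 129 CPM (-0.99). Camera called the list (adjusted p = 0.00036), and the call was lost with an estimated correlation (adjusted p = 0.096).

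Mitochondrial energy genes did not move as lists. Of 26 tricarboxylic acid cycle genes, 8 rose, 13 fell and 5 were not called. Their median was -0.12, their mean 0.03 and the direction of the camera test was down (adjusted p = 1.0). The pyruvate carboxylase gene Pcx rose from 49.8 to 327 CPM (2.71) and the isocitrate dehydrogenase gene Idh2 from 43.8 to 183 CPM (2.07), while Dlat, a subunit of pyruvate dehydrogenase, fell from 116 to 52.4 CPM (-1.15) and the malate dehydrogenase gene Mdh2 from 172 to 88.2 CPM (-0.96). Of 52 oxidative phosphorylation genes, 14 rose, 19 fell and 19 were not called, with a median of -0.06 (camera adjusted p = 0.53). The complex I genes Ndufa5 (0.65) and Ndufb2 (0.46) rose, and the ATP synthase gene Atp5b (-0.99) and complex III gene Uqcrb (-0.77) fell. Ndufa5 and Ndufb2 lie on chromosome 6, whose tested genes had a median of 0.42. Uqcrb lies on chromosome 13 (median -0.54) and Atp5b on chromosome 10 (median -0.11). Ndufb2 was not called without KMT2D KO replicate 2 (log2 fold change 0.37).

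In the IGF signalling list, 12 of 23 genes rose, 6 fell and 5 were not called, with a median of 0.33 (camera adjusted p = 0.22). Igfbp5, which encodes a secreted IGF-binding protein (chromosome 1, 72904639 to 72921439), fell from 6.30 ± 1.24 to 2.90 ± 0.215 CPM (SD, n = 3), a log2 fold change of -1.12 (SE 0.17, adjusted p = 3.3e-05). Igf1r, the IGF1 receptor gene (chromosome 7, 75097143 to 75378553), had 174 ± 10.8 and 185 ± 10.8 CPM, a log2 fold change of 0.09 that was not called (adjusted p = 0.19). Without KMT2D WT replicate 3 it was 0.15 and called (adjusted p = 0.022, where all alternatives gave 0.022 to 1). The growth factor gene Igf2 rose from 1.68 ± 0.591 to 211 ± 3.13 CPM (7.01), and Igfbp2 rose from 0.252 to 8.59 CPM (5.04). Igf2 overlaps Igf2os, and fragments that overlap both are left out by default, so the Igf2 counts may be too low. The RNA-binding protein gene Igf2bp1 fell from 16.4 to 0.0334 CPM (-8.73) and the protease gene Htra1 from 1670 to 432 CPM (-1.95).

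Extracellular matrix genes were higher in 26 of 38 cases, lower in 10 and not called in 2, with a median of 1.16. The basement membrane gene Nid2 rose from 4.79 to 302 CPM (5.99) and the matricellular gene Postn from 4.98 to 247 CPM (5.64). The metalloproteinase inhibitor genes Timp3 (2952 to 170 CPM, -4.12) and Timp2 (4027 to 962 CPM, -2.07) fell. Camera called the list (adjusted p = 8.4e-14), and the call was lost with an estimated correlation (adjusted p = 0.10). Of 22 epithelial-mesenchymal transition genes, 10 rose, 7 fell and 5 were not called, with a median of 0.12 (camera adjusted p = 0.38). They included the smooth muscle actin gene Acta2 (372 to 2107 CPM, 2.50), Mmp2 (824 to 2333 CPM), Twist2 (65.0 to 3.97 CPM, -4.04) and S100a4 (1471 to 790 CPM, -0.90).

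Neural crest and undifferentiated melanoma genes were higher in 14 of 24 cases, lower in 7 and not called in 3, with a median of 0.42. The transcription factor genes Sox2 (0.101 to 10.9 CPM, 6.78) and Tfap2b (3.31 to 120 CPM, 5.18) rose, and the intermediate filament gene Nes (226 to 3.07 CPM, -6.20) and the neurturin receptor gene Gfra2 (29.0 to 2.79 CPM, -3.38) fell. Camera called the list (adjusted p = 0.0054), and the call was lost with an estimated correlation (adjusted p = 0.54). Pigmentation genes were scarce in both groups, since 13 of 21 had under 1 CPM in each. Of the 10 that could be tested, 4 rose, 3 fell and 3 were not called. Their median was 0.34 and their mean 0.12, while the direction of the camera test was down (adjusted p = 1.0). The median turned negative without KMT2D WT replicate 3 (-0.32) and without KMT2D KO replicates 1 (-0.26), 2 (-0.27) or 3 (-0.04). The low-count filter was run anew each time, so the members tested may have differed between these medians. Mitf, the melanocyte master regulator, rose from 15.4 to 53.2 CPM (1.79) and the melanosome transport gene Rab27a from 0.482 to 4.67 CPM (3.28). Slc24a5, which shares exonic sequence with Myef2, fell from 56.0 to 2.74 CPM (-4.33) and Syngr1 from 3.21 to 0.935 CPM (-1.78). Chosen after their values were seen, the pigment enzyme genes Tyr, Tyrp1 and Dct had at most 0.0765 CPM in either group, and Gpnmb had 425 and 617 CPM.

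**Figure D2:**
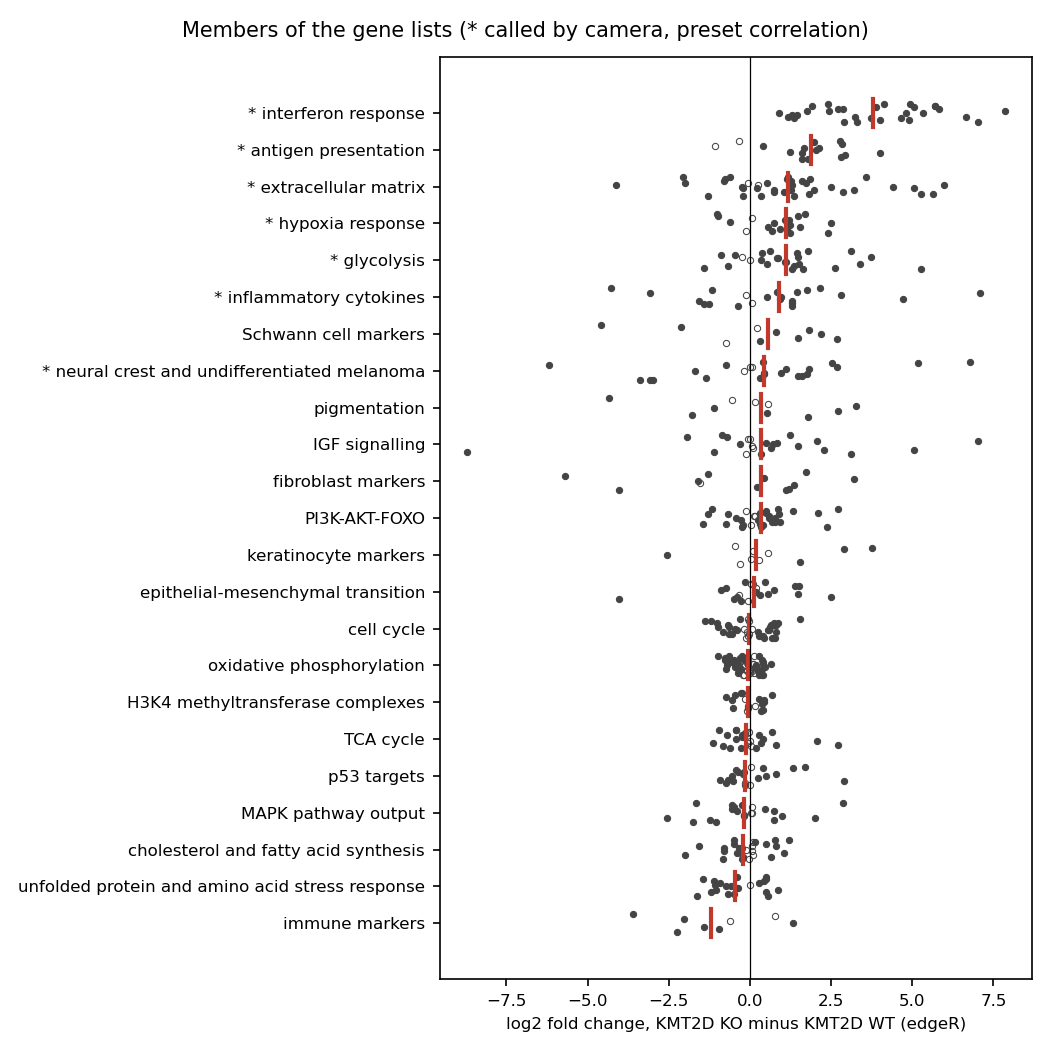
Log2 fold changes (KMT2D KO minus KMT2D WT, horizontal axis) of the tested members of the 23 gene lists on the vertical axis. Filled points were called by edgeR, open points were not, red bars are medians and asterisks mark lists called by camera with a preset correlation. All 30 interferon genes lie above 0, with a median of 3.80, while the medians of most other lists lie near 0.

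Signalling and stress lists held genes that changed in both directions. Of 32 PI3K-AKT-FOXO genes, 19 rose, 9 fell and 4 were not called, with a median of 0.33 (camera adjusted p = 0.11). The pseudokinase gene Trib1 rose (43.0 to 283 CPM, 2.72), while Trib3 (-1.43) and the kinase subunit gene Pik3cb (-1.29) fell. Of 21 MAPK output genes, 6 rose, 11 fell and 4 were not called, with a median of -0.17 (adjusted p = 0.29). The feedback inhibitor gene Spry1 (2.23 to 16.4 CPM, 2.86) and the early response gene Egr1 (197 to 784 CPM, 1.99) rose, while Spry4 (61.5 to 10.4 CPM, -2.56) and the phosphatase gene Dusp4 (83.4 to 24.8 CPM, -1.75) fell. Of 22 unfolded protein and amino acid stress genes, 7 rose, 14 fell and 1 was not called, with a median of -0.45 (adjusted p = 0.11). The cystine transporter gene Slc7a11 fell from 388 to 126 CPM (-1.62), and its partner Slc3a2 (0.87) and the stress factor gene Atf3 (0.54) rose. Of 20 p53 target genes, 7 rose, 10 fell and 3 were not called, with a median of -0.16, a mean of 0.15 and an upward camera direction (adjusted p = 0.83). Perp (2.90) and Btg2 (1.71) rose, and Ccng1 (-0.93) and Gadd45a (-0.74) fell.

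Growth and lipid genes likewise split. Of 36 cell cycle genes, 16 rose, 12 fell and 8 were not called. Their median was -0.04, their mean 0.03 and the direction of the camera test was down (adjusted p = 0.83). The mitotic checkpoint gene Bub1b (1.53) and Cdc25c (0.87) rose, and the replication helicase gene Mcm4 (79.0 to 30.5 CPM, -1.37) and Ccne2 (-1.20) fell. Of 27 cholesterol and fatty acid synthesis genes, 7 rose, 14 fell and 6 were not called, with a median of -0.21 (adjusted p = 0.52). The desaturase genes Fads2 (1.21) and Fads1 (1.06) rose, and Idi1 fell (-1.99). Of 18 genes of H3K4 methyltransferase complexes, 7 rose, 6 fell and 5 were not called, with a median of -0.06 (adjusted p = 0.91). Kdm6a, a subunit of the Kmt2d complex, rose from 28.4 to 45.4 CPM (0.68) and Men1 from 51.9 to 70.3 CPM (0.44), while Paxip1 fell from 31.2 to 18.6 CPM (-0.74) and Setd1a from 58.5 to 40.0 CPM (-0.55).

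Markers of other cell types gave no list called by camera. Of 12 fibroblast markers, 7 rose, 4 fell and 1 was not called, with a median of 0.33, a mean of -0.41 and an upward camera direction (adjusted p = 0.53). The collagen genes Col3a1 (836 to 7661 CPM, 3.20) and Col1a2 (2808 to 9385 CPM, 1.74) rose, and Dpt (44.8 to 0.839 CPM, -5.69) and Twist2 fell. Of 10 Schwann cell markers, 6 rose, 2 fell and 2 were not called, with a median of 0.55 (adjusted p = 0.17), among them Egr2 (2.68), Ncam1 (2.18) and S100b (-4.60). Of 10 keratinocyte markers, 3 rose, 1 fell and 6 were not called, with a median of 0.17 (adjusted p = 0.53), among them Trp63 (3.77), Perp (2.90) and Dsp (-2.55). The 8 tested immune markers (adjusted p = 0.53) included Cd68 (9.03 to 2.21 CPM, -2.02) and Csf1r (2.56 to 0.957 CPM, -1.41), and 12 of the 15 in the list had under 1 CPM in each group. Of 14 cerebellum markers, 3 could be tested and all 3 rose, but none exceeded 2.35 CPM (Cbln3, 3.05, and Syt1, 2.06, were named by the rule). Endothelial and muscle markers each had 4 tested genes, 1 higher, 1 lower and 2 not called, and the endothelial gene that rose was Egfl7, from 3.69 to 8.95 CPM (1.28). Of 34 homeobox cluster genes, all had under 1 CPM in both groups, and of the 3 tested 1 rose, 1 fell and 1 was not called. The 4 Y-linked genes were lower in KMT2D KO, with Ddx3y at 114 ± 9.81 and 0.613 ± 0.184 CPM (SD, n = 3; -7.58) and Uty at 34.8 and 0.177 CPM (-7.60), and Xist stayed under 1 CPM in every library.

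By camera with the preset correlation, 7 of 23 lists were called, all higher in KMT2D KO, and with an estimated correlation 2 were. The number of members called, adjusted over the list alone, was the same as that over all genes except in 4 lists, where it rose to 31 for PI3K-AKT-FOXO, 29 for the cell cycle, 21 for inflammatory cytokines and 12 for fibroblast markers. In each called gene named here other than Kmt2d, all libraries of 1 group lay above all libraries of the other.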

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

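The alternatives without the 4 abundant non-coding RNAs and with calls centred per chromosome were chosen after the data were seen. Under the other settings than glmTreat, 9371 to 10798 genes were called, and 9217 to 10333 of them were shared with the 10345 of the main setting, all with the same sign. Against an absolute log2 fold change of 1 (glmTreat), 2823 genes were called, 1479 higher and 1344 lower, because that test asks for larger changes. Leaving out each library in turn gave 9542 to 10798 genes, 4779 to 5370 higher and 4763 to 5428 lower. Scaling by library size alone moved the median of all genes by -0.11 and the share of calls that were higher from 49.9% to 42.4%. With calls centred per chromosome, 3667 genes passed an absolute log2 fold change of 1 instead of 3902.

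The Kmt2d log2 fold change of -0.27 was no longer called under glmTreat (-0.27, adjusted p = 1) and without KMT2D KO replicate 2 (-0.21), and ranged from -0.34 to -0.17 without each library in turn. The cause was not tested. The planned test of single Kmt2d exons was not run, since the files hold gene totals.

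Of the 23 lists, 7 were called with RLE factors, library size alone, a mean CPM of at least 1 (immune markers not tested), the block, without the 4 non-coding RNAs and without each library in turn. Lists were not tested without a low-count filter. With an estimated correlation, which does not refit fold changes, 2 were called. Those lost were glycolysis (median 1.11), extracellular matrix (1.16), hypoxia (1.11), neural crest (0.42) and inflammatory cytokines (0.88). Their estimated correlations were 0.18, 0.12, -0.02, 0.24 and 0.06, in the same order. That of hypoxia lay below the preset 0.01, so a higher correlation does not account for the loss of that list. Its unadjusted camera p still rose from 7.7e-05 to 0.013. That of antigen presentation, with an estimated correlation of 0.0023, rose from 4.1e-11 to 0.0022. The estimated form thus gave larger p-values for these 2 lists without a higher correlation, and a lost call is not in itself a sign of correlated genes. No other cause was tested. Fry, which does not compare a list with other genes, called 18 lists directionally and 23 as mixed. The number of called chromosomes was 6 with RLE factors, library size alone, a mean CPM of at least 1, an estimated correlation and without each library in turn, the alternatives tried for chromosomes, but chromosomes 13 and 18 were not called with an estimated correlation and 2 and 8 were.

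Over the 102 genes other than Kmt2d that the rule took, 1607 values under alternatives kept the call and, where called, the direction, 24 lost the call (under glmTreat, and Ndufb2 also without KMT2D KO replicate 2), 1 gained it and 0 reversed. Lists not called gave 196 values on the same side of the threshold and 27 that gained a call, the latter all under fry. Medians near 0 of the cell cycle, H3K4 and oxidative phosphorylation lists changed sign without KMT2D WT replicate 2 (0.01), KMT2D WT replicate 3 (0.02) and KMT2D KO replicate 3 (0.0055).

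There was little sign that replicate numbers paired the samples. Between the groups, deviations of libraries with the same number correlated by 0.0084 to 0.015. Those with other numbers correlated by -0.017 to 0.0070, slightly lower. With the replicate block, 10368 genes were called.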

Other observations

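Genes in this paragraph were looked up after the data were seen. All 8 genes examined of the H19-Igf2 and Dlk1-Dio3 imprinted domains rose in KMT2D KO, with log2 fold changes of 4.86 to 8.79 and a median of 7.01. Beside H19 and Igf2 these were Dlk1, Rtl1, Dio3 and the non-coding RNA genes Meg3, Rian and Mirg. Meg3 rose to 90.8 ± 3.77 CPM and Dio3 to 267 ± 9.39 CPM (SD, n = 3). Camera called the group (adjusted p = 6.1e-26, and 0.0017 with an estimated correlation), a test on genes picked because they had risen. Of 26 other imprinted genes tested, 11 rose, 8 fell and 7 were not called, with a median of -0.02. Their values ranged from -4.79 (Peg12) to 7.63 (Ndn, 0.0752 to 15.9 CPM), so strong changes were not confined to the 2 domains. Of 13 tested Serpinb protease inhibitor genes, 12 fell and 1 rose, with a median of -2.34. They include Serpinb9e, which was among the 6 largest falls, so this count is no independent test. Most of them lie on chromosome 13, whose tested genes had a median of -0.54. Serpinb2 fell from 221 to 5.55 CPM (-5.31) and Serpinb9b from 323 to 9.42 CPM (-5.10), while Serpinb8 rose (1.03). Reads shared between Serpinb9 copies leave the values of that family uncertain.

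The tests of explanations below were chosen after the results were seen, except the counts of other splits of the libraries. The 6 libraries can be split into groups of 3 in 10 ways, which are too few for a share under 0.05. Only 1 split, the real one, gave as many called genes, with 10345 against a highest count of 0 in any other (edgeR, and 11 to 53 genes at an unadjusted p under 0.05). Every other split put libraries of both groups on each side, so the difference between the groups added to the spread within a side. Few called genes were therefore bound to result, and these counts do not test chance. For lists, 1 split reached the real count of 7, and the highest other count was 6. For chromosomes, all 10 splits reached the real count of 6, and the highest other count was 9. Part of the difference between the groups remained between the sides of the other splits. Their list and chromosome counts are therefore no measure of chance.

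The rise of all 30 interferon-stimulated genes was set against immune cells in the KMT2D KO cultures, library scaling and the separate origin of the cells. The tested immune markers had a median of -1.19, the opposite direction, with Cd68 at 2.21 CPM in KMT2D KO. The lowest list median over the scalings tried was 3.69, against 3.80 in the main setting. These scalings differed little, since library size alone moved the median of all genes by -0.11. They could not have removed the rise, so the check speaks only to the scalings tried. Mean log2 CPM of the list was 2.59 to 2.63 in KMT2D WT libraries and 6.34 to 6.38 in KMT2D KO libraries. Per the labels, the cells of the groups came from different mice. The Y-linked genes, which Kmt2d deletion would not be expected to silence, had a median of -7.58. Whether this came with the mice of origin or from loss of the Y chromosome was not tested. The labels do not give more than 1 cell source of each genotype. An effect of the Kmt2d genotype therefore cannot be told apart from other differences between the cells.

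Median log2 fold changes differed between chromosomes. They were lower on chromosomes 13 (-0.54), 18 (-0.50), 16 (-0.44), 5 (-0.36) and 9 (-0.30) and higher on chromosome 6 (0.42), the 6 chromosomes called by camera with a preset correlation of 0.01. With an estimated correlation, chromosomes 13 (adjusted p = 0.070) and 18 (0.058) were not called, while 2 (median 0.27, adjusted p = 0.013) and 8 (median 0.21, adjusted p = 0.028) were. Without the 1895 genes whose absolute log2 fold change was above 2, all 6 were still called in the same direction with the preset correlation, and chromosomes 2, 8 and 19 were called too. Camera called 6 or more chromosomes in every split, but the other splits keep part of the difference between the groups. Their counts therefore cannot say how strong these calls are. The medians without the 1895 genes were -0.50 on chromosome 13, -0.48 on 18, -0.41 on 16, -0.33 on 5, -0.28 on 9 and 0.38 on 6. A few genes hardly move a median, so these values could scarcely have come out otherwise. Fold changes were below 0 in 72.4% of tested genes on chromosome 13, 73.8% on 18 and 75.2% on 16. The share was 69.6% on 5, 68.0% on 9 and 28.4% on 6, so the shifts were not confined to a few strongly changed genes. When each chromosome's genes were divided at the median expression and at the median position, 24 of 24 medians of the called chromosomes kept the chromosome's sign. So did 55 of 56 medians of the 14 chromosomes not called (p = 0.7, Fisher test), so this says nothing about gene dosage, and unequal chromosome copies in the cells of the groups stay open. The variance of the medians was 0.0726, against at most 0.0035 in 10000 permutations of genes over chromosomes (permutation p = 1e-04, the smallest they can give), a test that takes genes as independent.

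Of 21 pigmentation genes, 13 were under 1 CPM in both groups and 3 at 10 CPM or more in both, while matrix genes such as Col1a2 were abundant. The labels' mention of cerebellar tissue was tested first. The most abundant of 14 cerebellum markers reached 2.35 CPM in a group, which argues against cerebellum as the main source of this RNA. Fibroblasts in the cultures could also give such a profile, and 6 of 12 fibroblast markers were at 10 CPM or more in both groups, among them Pdgfra (557 and 1208 CPM) and Dcn (118 and 138 CPM), whereas Lum (1.30 and 0.527 CPM) and Fap (0.238 and 0.549 CPM) were not. Fibroblasts and tumour cells with fibroblast-like expression cannot be told apart from these totals, since tumour cells with low pigment gene expression can express the same markers.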
